A study of Homo sapiens with 6 samples.

How the data were processed

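RNA from THP-1 cells, an established human monocytic leukaemia line, was measured in 6 libraries, 3 untreated and 3 given continuous low-intensity ultrasound. Per the labels' protocols, RNA had an integrity number of at least 9.0, poly(A) RNA was made into strand-specific libraries, and these were sequenced as read pairs of 101 bases. The labels name a pair of sequencing instruments without saying which library ran on which, and they name no culture date or library batch. They call the libraries biological replicates, but do not say whether a replicate number marks a shared culture.

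The authors deposited a table per gene and a table per transcript for every library, with estimated counts, TPM and FPKM. DRAGEN, STAR and featureCounts with genome build GRCh38.p14 are named, without versions or roles, per the submitters' processing notes. The layout of the deposited tables is that of salmon-type estimates, which need not be whole numbers. The annotation release and the strand setting are not given in the sources used here, so values of overlapping, antisense or near-identical genes are uncertain. The TPM and FPKM columns were not used. The deposited estimated counts of 61544 genes were rounded to whole numbers before testing. Library totals were 26607834, 30677526 and 30835706 for the untreated and 38870892, 38234158 and 38069869 for the ultrasound libraries. The transcript table (246624 transcripts) served for alternatives. List symbols were matched through the deposited names or the reference name table, which held 61445 of the 61544 gene identifiers, and all 1124 distinct list genes were found. Coordinates are those of NCBI RefSeq on GRCh38.p14.

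Genes were filtered with filterByExpr, which left 19692, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, group as the only term, all 6 libraries, R 4.3.3). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the log2 change divided by the square root of the F statistic. CPM values are TMM-scaled, and errors are SDs of 3 libraries. The 43 gene lists were tested on log2 CPM with camera in limma 3.58.1, with a preset correlation of 0.01, for lists of at least 5 tested members and with adjustment over all lists. Camera with an estimated correlation and fry, a self-contained test of whether genes move one way, were run beside it. The lists, the tests and the rule for named genes were set before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with a real symbol, a mean of at least 5 CPM and no overlap between groups. It added, by smallest adjusted p, up to 5 called members per direction of the M1 and of the M2 list. For every other list with at least 3 called members, or called by camera, it added up to 2 per direction, of which the text leaves some out. The result for 1 gene that the rule names is not reported here.

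The gene and list tests were tested on simulated data with the real means and library sizes. Each gene had a dispersion shared by both groups, unlike the real groups, and far fewer genes were changed than were called in the real data. Of 200 genes changed by known amounts among 19216 tested, the test recovered 34% of those changed 1.5-fold, 80% at 2-fold, and 100% at 4-fold and 8-fold. It made 168 calls, of which 11 were false (6.55%). Both lists shifted 1.5-fold were called, and 0 other lists were called by camera. Genes were simulated independently of each other, so this does not show how often camera calls lists of correlated genes falsely.

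Replicates were compared by a chi-square test of counts over genes. Untreated pairs gave 2.32 to 3.61 per gene and ultrasound pairs 28.4 to 117, so no pair agreed within sampling noise. Every library was kept as a replicate because the labels call them so. The biological coefficient of variation was 0.0351 in the untreated and 0.181 in the ultrasound group. Excess over counting noise does not show that the untreated libraries came from separate cultures, and their small spread leaves this in doubt. P-values then measure only the spread between these samples, which may be technical. Alternatives set beforehand were other scaling (RLE, upper quartile, library size), other filters, DESeq2 1.42.0, limma-voom, a gene length offset, transcript sums, omission of mitochondrially encoded genes, protein-coding genes alone, a replicate block, omission of each library, a threshold of 0.01 and a test against a 1.2-fold change. A correction for length and GC content, separate spreads per group and thinning to equal depth were added after the data had been seen. GC content and biotype came from GENCODE v29, an annotation that is not stated to be the authors', and covered 97.5% of tested genes. Figures were drawn with matplotlib 3.10.9.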

Results

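Gene expression was measured by RNA sequencing in macrophages derived from THP-1 cells, a human monocytic leukaemia line. The cells had been differentiated with phorbol ester (PMA, 200 nM) and driven to an inflammatory, M1-type state with fibronectin fragments (25 µg/mL), which are fragments of a matrix protein released in damaged tissue. They were then held in hydrogels of 1.2% alginate, with 10 hydrogels per replicate. Of the 6 libraries, 3 came from untreated hydrogels and 3 from hydrogels that received continuous low-intensity ultrasound (cLIUS; 5 MHz, 2.5 Vpp, 20 min per application, 4 applications per day) for 72 h. Library totals ranged from 26607834 to 30835706 estimated counts in the untreated group and from 38069869 to 38870892 in the cLIUS group. The labels state the question, which is how ultrasound alters gene expression of these stimulated macrophages. Cells without fibronectin fragments were not analysed here, so all levels are relative to stimulated, untreated cells.

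The 2 groups differed widely. The genes for complement C1q, CCR2 and FPR1 rose after cLIUS, whereas IL1B, osteopontin (SPP1) and INHBA fell. Of 19692 genes tested, 7804 changed (39.6%; edgeR quasi-likelihood, Benjamini-Hochberg adjusted), 3980 higher and 3824 lower after cLIUS. At least a 2-fold change was reached by 1315 of the higher and 1653 of the lower genes, but among the 11933 genes with a mean of 5 CPM or more by 623 higher and 367 lower. Groups did not overlap for 53.5% of tested genes, where chance gives 10%. With library size as the only scaling, 3073 genes were higher and 5053 lower, and the median of all genes moved by -0.12 (log2). Without cLIUS replicate 3, the number of lower genes was 2517. Of the 1653 genes that fell at least 2-fold, 883 had a mean under 1 CPM, and the untreated libraries also had more genes with at least 1 count (35741 to 36575) than the cLIUS libraries (31212 to 32276). The first principal component, with 77% of the variance, separated the groups, and the second (12.3%) separated cLIUS replicates 1 and 2.

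The 10 largest rises included those of the 3 genes for C1q, the recognition molecule of the classical complement pathway, which are neighbours on chromosome 1 (GRCh38.p14, 22636463 to 22661637). C1QB had the largest and rose 116-fold from 0.154 ± 0.0286 to 18.2 ± 3.51 CPM (SD, n = 3 per group), C1QC 42.1-fold to 70.45 ± 12.7 CPM and C1QA 32.9-fold to 35.3 ± 7.11 CPM. The others were MS4A6A (46.0-fold), the adhesion molecule JAML (43.3-fold), the chemokine receptor CCR2 (38.0-fold), the pore-forming phagocyte protein MPEG1 (31.5-fold), the formyl peptide receptor FPR1 (28.8-fold), the B-cell chemoattractant CXCL13 (24.6-fold) and the complement receptor CR1 (24.4-fold). All 10 genes started from low untreated means, between 0.154 (C1QB) and 2.49 CPM (MPEG1), so the size of these folds rests on small denominators. The edgeR adjusted p of these 10 genes lay between 1.05e-06 (JAML, MPEG1) and 1.45e-05 (CR1).

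The largest falls were found for IGFN1 (45.6-fold lower, from 107 ± 18.3 to 2.32 ± 2.53 CPM), the collagen gene COL22A1 (28.01-fold), SCG5 (25.3-fold), the potassium channel gene KCNN3 (21.5-fold), RADX (20.9-fold) and STC1 (18.7-fold). The chemokine gene CCL4L2 fell 17.2-fold, but it is a near-identical copy of CCL4 and its counts are uncertain. GREM1, an antagonist of bone morphogenetic proteins, fell 15.1-fold from 110 ± 1.26 to 7.23 ± 0.604 CPM. It lies on chromosome 15 (32718004 to 32745106) beside SCG5 (32641710 to 32697092). INHBA, a subunit of activin, fell 14.8-fold. SPP1, the gene for osteopontin on chromosome 4 (87975714 to 87983411), fell 14.7-fold from 647 ± 19.4 to 43.9 ± 6.09 CPM. The edgeR adjusted p of these genes was at most 4.81e-04 (IGFN1). Without cLIUS replicate 2 the log2 change of IGFN1 was -6.875, against -5.51 with all libraries.

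**Figure D1:**
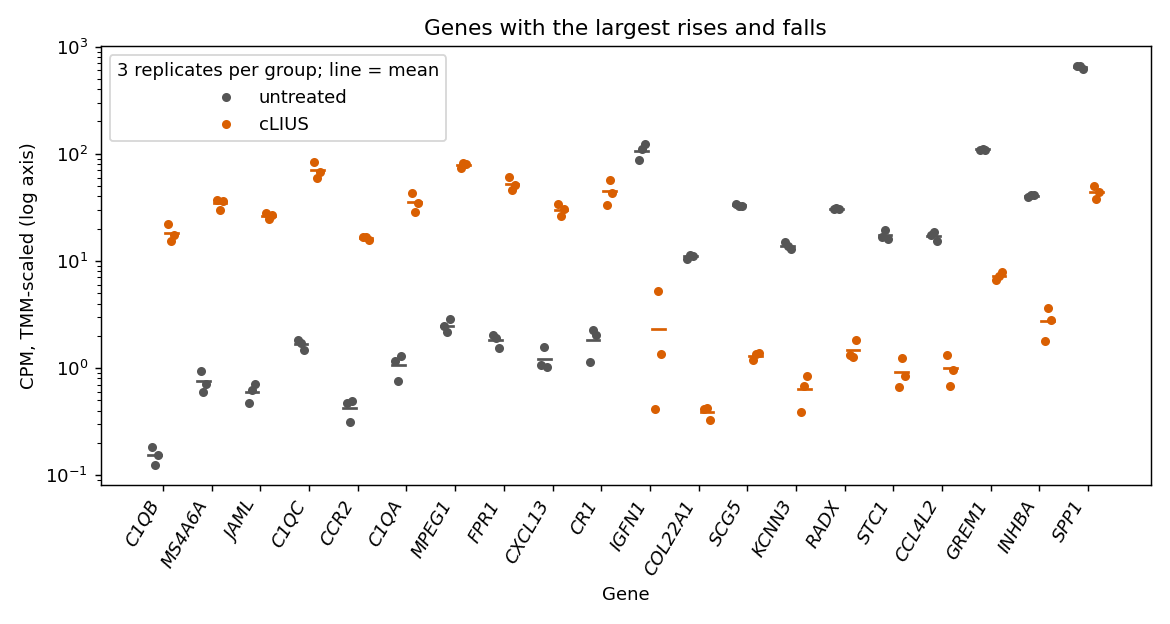
TMM-scaled CPM on a log axis of the 10 genes with the largest rises (left) and the 10 with the largest falls (right), with each of the 3 replicates per group as a point and the group mean as a line. The groups do not overlap for any of the 20 genes, and IGFN1 has the widest spread among cLIUS replicates relative to its mean (2.32 ± 2.53 CPM).

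M1 markers moved in both directions. IL1B, the gene for interleukin-1 beta (chromosome 2, 112829751 to 112836779), fell 12.01-fold from 1455 ± 75.7 to 121 ± 15.6 CPM (log2 change -3.59, SE 0.12, edgeR adjusted p = 1.16e-06). NOS2, the inducible nitric oxide synthase, was 11.96-fold lower and IL1A 3.67-fold, both from low levels (4.81 ± 0.849 to 0.398 ± 0.0828 CPM and 2.38 ± 0.542 to 0.646 ± 0.128 CPM). TNF fell 2.59-fold (42.8 ± 4.25 to 16.5 ± 2.63 CPM) and the prostaglandin synthase gene PTGS2 1.94-fold. In the other direction, CD38 rose 7.10-fold, the lipopolysaccharide receptor TLR4 3.29-fold, the costimulatory molecule CD86 3.01-fold (24.4 ± 0.977 to 73.5 ± 6.67 CPM), SLAMF7 2.51-fold and the guanylate-binding protein GBP5 2.19-fold. Of 25 M1 markers tested, 14 rose, 6 fell and 5 did not pass, and 14 and 6 did so adjusted over the list alone. The list as a whole was higher after cLIUS (median log2 change 0.89, camera adjusted p = 0.014), and this call was lost with an estimated correlation (adjusted p = 0.24).

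M2 markers also moved in both directions. The pattern recognition receptor CLEC7A rose 9.56-fold, the complement receptor VSIG4 7.62-fold (19.3 ± 0.676 to 147 ± 23.2 CPM), the coagulation factor subunit F13A1 3.71-fold and the lectin CD209 2.53-fold. The lectin CLEC10A rose from 0.0518 ± 0.0473 to 1.36 ± 0.201 CPM. The scavenger receptor MSR1 fell 4.71-fold, the mannose receptor MRC1 4.20-fold, the interleukin-1 receptor antagonist IL1RN 2.57-fold, TGM2 1.99-fold and TGFB1 1.60-fold. Of 26 tested, 17 rose, 6 fell and 3 did not pass, with 17 and 6 adjusted over the list alone. The list was higher (median log2 change 0.87, camera adjusted p = 0.0052; adjusted p = 0.22 with an estimated correlation). Under a filter of 1 CPM on average the list missed the threshold (camera adjusted p = 0.054).

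**Figure D2:**
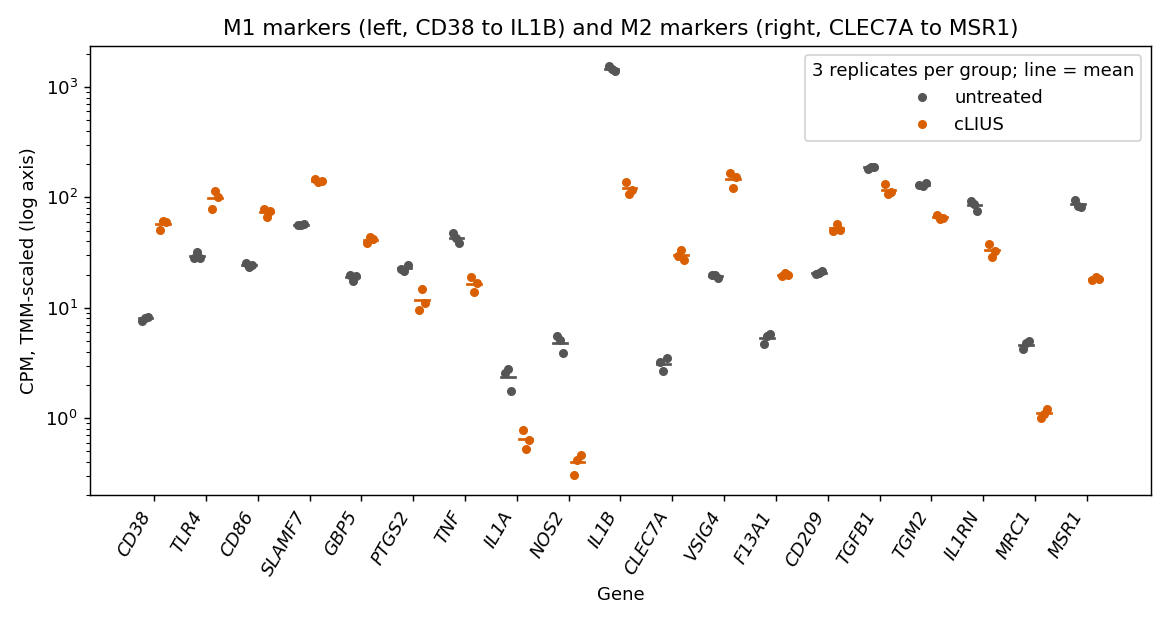
TMM-scaled CPM on a log axis of the named M1 markers (CD38 to IL1B) and M2 markers (CLEC7A to MSR1), with 3 replicates per group as points and the mean as a line; CLEC10A is left out because a replicate had 0 counts. IL1B falls from 1455 to 121 CPM, while CD86 and VSIG4 rise, to 73.5 and 147 CPM.

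Chemokine genes were divided. CCL4 fell 7.36-fold and CCL3 6.11-fold, both chemoattractants of monocytes with near-identical copies in the genome, while CXCL13 and CXCL16 (2.94-fold) rose. Of 19 tested, 9 rose and 6 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.52), except with no filter on low counts (adjusted p = 0.032). Of 28 NF-kB target genes, 9 rose and 5 fell (9 and 6 adjusted over the list alone). CD83 fell 4.30-fold and IRAK2 2.82-fold, and TNFAIP2 rose 2.08-fold and BCL3 1.77-fold. That list was not called (camera adjusted p = 0.59), and its median (0.12) and mean (-0.05) differed in sign. Inflammasome genes were higher as a list (10 rose and 3 fell of 20; camera adjusted p = 0.013, and adjusted p = 0.24 with an estimated correlation). MEFV rose 4.54-fold and TXNIP 2.19-fold, while IL1B, which is a member, and PANX1 (2.38-fold) fell. Genes of feedback and resolution were higher too (15 rose and 2 fell of 27; camera adjusted p = 1.9e-04, and adjusted p = 0.40 with an estimated correlation), with FPR2 18.2-fold and the interleukin-10 receptor IL10RA 7.18-fold higher, and IL1RN and TGFB1 lower.

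The lists for antigen presentation, interferon response and complement were each higher by camera with the preset correlation. Of 14 tested members of the list for antigen presentation by MHC class II, 12 rose and 0 fell. Among them were HLA-DMB (8.20-fold, 0.786 ± 0.0149 to 6.47 ± 0.374 CPM) and CD1D (7.12-fold, 10.3 ± 0.363 to 73.4 ± 3.71 CPM), which is not itself a class II gene. The list median was 1.498 (camera adjusted p = 1.1e-06, and adjusted p = 0.24 with an estimated correlation). The list for antigen presentation by MHC class I was also higher (11 rose and 2 fell of 20, median 0.31, camera adjusted p = 0.017, and adjusted p = 0.54 with an estimated correlation). Of 40 interferon-stimulated genes, 25 rose and 1 fell (camera adjusted p = 1.4e-06, and adjusted p = 0.13 with an estimated correlation), with MX1 6.15-fold and OAS2 2.58-fold higher and HERC6 1.32-fold lower. Of 20 complement genes, 14 rose and 2 fell (camera adjusted p = 2.2e-06, and adjusted p = 0.24 with an estimated correlation). Those that fell were the anaphylatoxin receptors C5AR1 (1.89-fold) and C5AR2 (1.72-fold). Scavenger and efferocytosis genes were higher as a list (17 rose and 7 fell of 28; camera adjusted p = 0.0013, and adjusted p = 0.18 with an estimated correlation), with COLEC12 8.02-fold higher and MSR1 and the integrin ITGB3 (3.63-fold) lower.

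Most tested markers of neutrophils, myeloid progenitors and dendritic cells also rose, while those of osteoclasts moved both ways. Of 19 neutrophil markers 12 were tested. Of these, 10 rose and 2 fell, with a median log2 change of 3.16 (camera adjusted p = 2.2e-06, and adjusted p = 0.13 with an estimated correlation). Those that rose include FPR1 and the granulocyte growth factor receptor CSF3R (6.91-fold), while the protease MMP8 fell 1.91-fold and MGAM 2.01-fold. CSF3R is also in the list of myeloid progenitors and undifferentiated monocytes, so its rise is not particular to neutrophils. Of 20 genes of myeloid progenitors and undifferentiated monocytes, 13 rose and 1 fell (camera adjusted p = 4.3e-05, and adjusted p = 0.24 with an estimated correlation). The transcription factor GFI1 rose 3.78-fold and MYC fell 1.63-fold. Dendritic cell markers were higher (10 rose and 2 fell of 14; camera adjusted p = 0.0013, and adjusted p = 0.24 with an estimated correlation), with IRF8 7.82-fold higher and CD83 lower. Macrophage differentiation genes moved both ways (18 rose and 9 fell of 29; camera adjusted p = 0.013, and adjusted p = 0.49 with an estimated correlation). Lysozyme (LYZ) rose 7.57-fold to 2690 ± 321 CPM and SIGLEC1 12.5-fold, and the integrin subunit ITGAM fell 2.10-fold. Osteoclast markers were not called (7 rose and 5 fell of 14; camera adjusted p = 0.80). CA2 rose 8.79-fold. The fusion proteins OCSTAMP, at a low level (5.27 ± 0.374 to 0.351 ± 0.114 CPM), and DCSTAMP fell 14.8-fold and 3.33-fold. Lymphocyte markers (4 rose and 2 fell of 12; camera adjusted p = 0.37) and stromal, epithelial and erythroid markers (2 rose and 1 fell of 12; camera adjusted p = 0.26) were not called. Decorin (DCN) rose 6.33-fold to 99.01 ± 13.4 CPM, and KDR fell 1.65-fold.

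Genes of adhesion, matrix turnover and early transcription moved in both directions. Of 30 matrix proteases and inhibitors, 14 fell and 7 rose (camera adjusted p = 0.058, not called), and the list was called lower among protein-coding genes only (adjusted p = 0.039). The collagenase MMP1 fell 7.33-fold, while MMP25 rose 8.91-fold and MMP2 2.16-fold. Of 31 integrin and focal adhesion genes, 14 fell and 8 rose (camera adjusted p = 0.054, not called), with ITGA3 2.43-fold lower and ITGB2 1.71-fold higher. That list was called lower with a filter of 1 CPM on average (camera adjusted p = 0.033), among protein-coding genes only (0.033) and at equal depth (0.040). Matrix and TGF-beta response genes were not called (8 rose and 10 fell of 30; camera adjusted p = 0.95), with PDGFA 6.77-fold lower and SPARC 4.45-fold higher. YAP/TAZ and SRF targets were not called either (6 rose and 9 fell of 29; camera adjusted p = 0.95). ANKRD1 fell 10.4-fold and NT5E 6.04-fold, and CNN2 rose 3.47-fold. The list of mechanosensitive channels is broad and also holds STIM1, which is not a channel. Of its 24 tested genes, 11 rose and 6 fell (camera adjusted p = 0.21). TMC8 rose 2.82-fold and TRPM4 2.35-fold, while TRPA1 fell 2.85-fold at a low level (1.14 ± 0.170 to 0.399 ± 0.0275 CPM) and PANX1 also fell. Membership of the list does not show that TMC8 or TRPM4 senses force. Immediate early genes were lower as a list (4 rose and 15 fell of 32; camera adjusted p = 0.012, and adjusted p = 0.24 with an estimated correlation), with EGR2 7.77-fold and FOSL1 4.20-fold lower and ZFP36 2.20-fold higher. That list missed the threshold with no filter on low counts (adjusted p = 0.052).

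Stress programmes moved apart. Heat shock genes fell (1 rose and 14 fell of 26; camera adjusted p = 2.4e-04, and adjusted p = 0.31 with an estimated correlation), with HSPH1 1.86-fold and DNAJB4 1.77-fold lower, but HSPA6 rose 3.67-fold. Genes of the unfolded protein response of the endoplasmic reticulum rose (15 rose and 0 fell of 24; camera adjusted p = 6.1e-05, and adjusted p = 0.13 with an estimated correlation). The chaperone HSPA5 rose 1.91-fold to 2113 ± 46.9 CPM and HERPUD1 2.10-fold. Of 27 NRF2 targets, 5 rose and 11 fell (camera adjusted p = 0.11, not called), with TXNRD1 2.74-fold and SRXN1 2.49-fold lower and BLVRB 2.45-fold higher. Without cLIUS replicate 1 the NRF2 list was called lower (adjusted p = 0.036). The integrated stress response (5 rose and 8 fell of 34; camera adjusted p = 0.65), hypoxia (6 and 7 of 26; 0.80), p53 (7 and 6 of 26; 0.81), apoptosis (8 and 5 of 29; 0.90) and metallothionein and zinc (2 and 2 of 8; 0.81) lists were not called.

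Lysosomal genes rose as a group (27 rose and 3 fell of 37; camera adjusted p = 1.4e-06, and adjusted p = 0.36 with an estimated correlation), with cathepsin S (CTSS) 2.25-fold and GPNMB 2.27-fold higher and cathepsin L (CTSL) 2.49-fold lower. Cholesterol synthesis genes were higher (13 rose and 3 fell of 25; camera adjusted p = 0.0070, and adjusted p = 0.24 with an estimated correlation). DHCR7 rose 3.20-fold, but SQLE, an early oxygen-dependent enzyme of the pathway, fell 2.46-fold. LXR and lipid genes were not called (13 rose and 5 fell of 26; camera adjusted p = 0.058), with ABCG1 5.56-fold higher and FABP4 2.21-fold lower. Without untreated replicate 1, untreated replicate 2, cLIUS replicate 2 or cLIUS replicate 3 that list was called (camera adjusted p = 0.0497, 0.0434, 0.0445 and 0.0487). Glycolysis genes (8 rose and 5 fell of 22; camera adjusted p = 0.35) were not called. HK3 rose 6.53-fold and PFKP fell 1.83-fold. Of 51 nuclear genes of oxidative phosphorylation, 2 rose and 1 fell (camera adjusted p = 0.80). Of 13 mitochondrially encoded genes, 4 rose (camera adjusted p = 0.092). Without cLIUS replicate 2 both respiratory lists were called higher (adjusted p = 0.0089 and 0.0032).

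Cell cycle lists went opposite ways. Of 30 mitosis genes, 17 rose and 0 fell (camera adjusted p = 2.2e-04, and adjusted p = 0.38 with an estimated correlation), with CDC20 1.99-fold and KIF20A 1.81-fold higher. Of 32 DNA replication genes, 2 rose and 13 fell (camera adjusted p = 0.013, and adjusted p = 0.59 with an estimated correlation), with UHRF1 1.53-fold and RRM2 1.48-fold lower and CDT1 1.58-fold higher. The call of the replication list was lost without cLIUS replicate 2 (adjusted p = 0.16) and with no filter on low counts (adjusted p = 0.27). Replication-dependent histones, whose transcripts lack poly(A) tails, were lower (0 rose and 12 fell of 19; camera adjusted p = 4.3e-05, and adjusted p = 0.24 with an estimated correlation). That list was set beforehand as a sign of poly(A) selection. Its fall may thus reflect a difference in preparation between the groups, which cannot be told apart from a cell cycle change here. Signs of dissociation and RNA quality were not called as a list (0 rose and 3 fell of 9; camera adjusted p = 0.52), though NEAT1 fell 2.05-fold and RN7SL1 1.71-fold. Of 76 ribosomal protein genes, 34 rose and 0 fell (45 adjusted over the list alone; camera adjusted p = 2.2e-06, and adjusted p = 0.68 with an estimated correlation of 0.99). The median of that list was 0.48, and 0.29 without cLIUS replicate 1. In cLIUS replicate 1 the shortest 20% of genes stood 0.29 above the untreated mean and the longest 20% at -0.36 (log2), while cLIUS replicate 2 tilted the other way. By GC content all 3 cLIUS libraries tilted the same way. From the lowest to the highest 20% of genes, replicate 1 went from -0.27 to 0.28, replicate 2 from -0.03 to 0.07 and replicate 3 from -0.13 to 0.14. The untreated libraries stayed close to their mean, so this GC trend goes with the treatment.

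**Figure D3:**
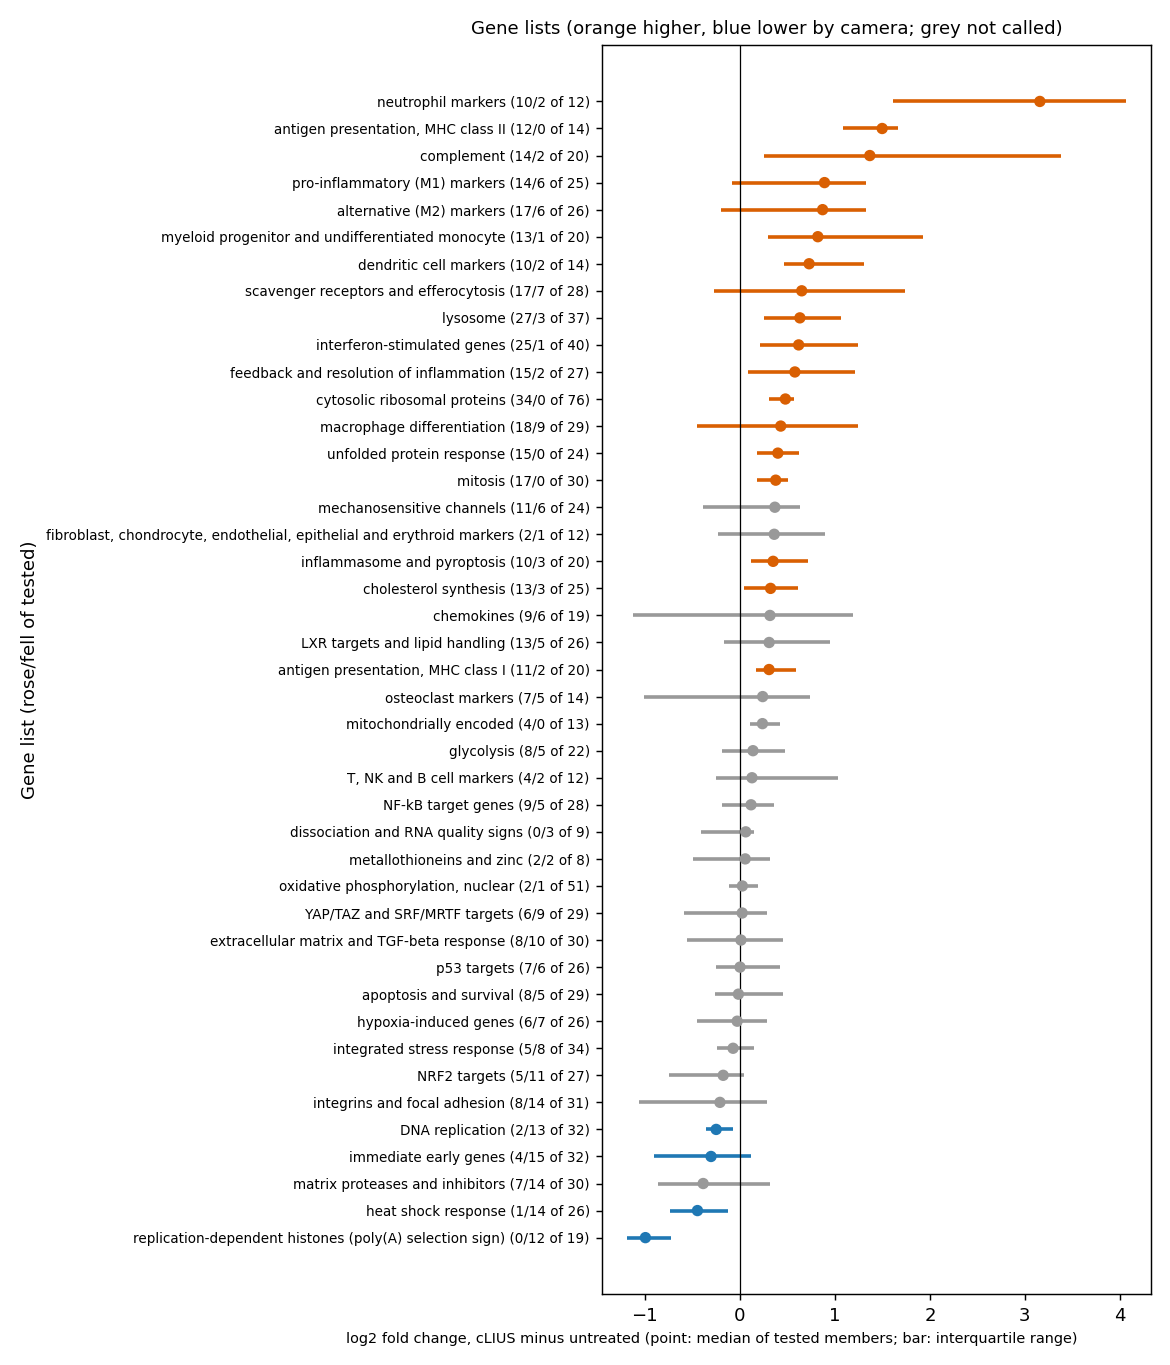
Median log2 fold change (point) and interquartile range (bar) of the tested members of each of the 43 gene lists, cLIUS minus untreated, with the number that rose and fell beside each name. Lists called by camera with the preset correlation are coloured, 18 higher and 4 lower, and neutrophil markers have the highest median (3.16).

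**Figure D4:**
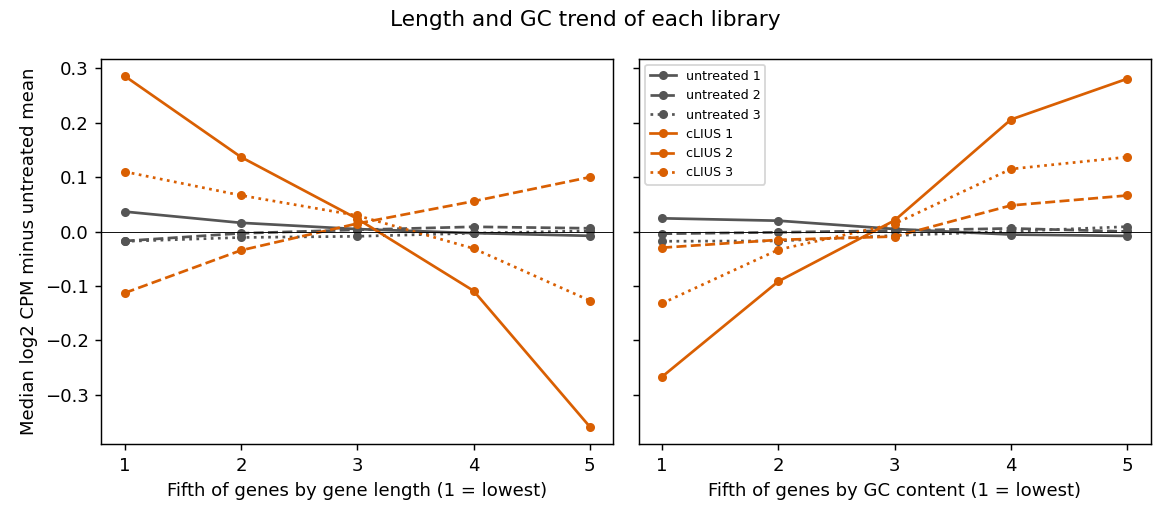
Median log2 CPM of each library minus the untreated mean, in 5 equal bins of genes by gene length (left) and by GC content (right). The untreated libraries lie near 0 throughout, and cLIUS replicate 1 has the steepest trend in both panels.

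With the preset correlation, 22 of the 43 lists were called, and 0 with an estimated correlation (camera; 7 at an unadjusted p under 0.05, and 30 by fry, which does not compare a list with other genes). For 6 lists the median, mean and test differed in sign. Over all lists, the count of called members differed by at most 11 between adjustment over all genes and adjusted over the list alone. Replicates were far more alike in the untreated group (biological coefficient of variation 0.0351) than in the cLIUS group (0.181), which leaves it in doubt whether the untreated libraries came from separate cultures. The p-values measure the spread between these samples only. The labels give no culture date or batch, so no preparation effect could be entered in the fit.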

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

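The correction for length and GC content, the separate spread per group and the thinning to equal depth were chosen after seeing the data; the other alternatives were set beforehand. Of 170 named genes, 161 kept their direction and call under all 22 alternatives in which they were tested, 9 lost the call under at least 1 and 0 reversed. The 7804 changed genes became 8848 after the length and GC correction (6871 shared), 7893 with separate spreads (7227 shared) and 7369 at equal depth (7105 shared). The cause was not tested unless the alternative's construction gives it. A threshold of 0.01 left 4668 genes, 2455 higher and 2213 lower. Genes at least 2-fold lower numbered 3010 with no filter on low counts, 812 with a filter of 1 CPM on average (against 954 at least 2-fold higher) and 976 among protein-coding genes only, which test more or fewer weakly expressed genes. With a library left out, the changed genes ranged from 5348 to 10958, the lower ones from 2517 (without cLIUS replicate 3) to 5406. Library size as the only scaling made 37.8% of calls higher, against 51.0%.

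With an estimated correlation 0 lists were called; the M1 list (median 0.89, adjusted p = 0.24) and the M2 list (0.87, 0.22) lost their calls. The M2 list also lost it with a filter of 1 CPM on average (0.67, adjusted p = 0.054), and 6 lists with medians above 0 gained one with no filter: chemokines (0.31, adjusted p = 0.032), mechanosensitive channels (0.022), glycolysis (0.022), nuclear oxidative phosphorylation (0.031), mitochondrially encoded genes (0.0032) and LXR and lipid genes (2.3e-04). NRF2 targets (0.028, lower) and mitochondrially encoded genes (0.014) gained one after the length and GC correction, and LXR and lipid genes with a gene length offset (0.047). By fry, YAP/TAZ and SRF targets (median 0.025, adjusted p = 0.023) and osteoclast markers (0.24, adjusted p = 0.013) were called lower, against the direction of camera. With replicate number as a block, 7627 genes were called (7109 shared) and 22 lists. Deviations of same-numbered libraries correlated by 0.249, 0.163 and -0.167. The highest correlations with another number were 0.185, 0.161 and 0.185. Replicates 1 and 2 thus correlated best with their own number, by little for replicate 2, and replicate 3 did not. Whether the numbers pair the samples stays open. In simulation with 200 of 19216 genes changed, 34% of 1.5-fold changes were recovered. The real data had far more calls (7804), which loosens the adjusted cut-off. This share thus does not give the recovery of the real test, and genes not called may still have changed 1.5-fold.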

Other observations

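The gene families of this paragraph, the test of sequencing depth and both tests of dilution were chosen only after the results had been seen. All 9 tested LILR receptor genes, which encode immunoglobulin-like receptors of leukocytes, rose, and their summed level went from 46.8 ± 0.825 to 185 ± 2.50 CPM of the library total. All 5 tested MS4A genes rose, as did 11 of 18 CLEC lectin genes (2 fell) and 7 of 13 SIGLEC genes (2 fell). S100 genes summed to 951 ± 38.9 CPM in untreated and 4600 ± 887 CPM in cLIUS libraries, with 7 of 15 higher and 2 lower. Of 7 EGF receptor ligand genes, 4 fell and 1 rose, and their sum went from 196 ± 6.33 to 64.0 ± 3.87 CPM. The medians of these families kept their sign under the other 3 scalings. Over all 6 libraries CAP1 (0.951% of counts), PPT1 (0.585%) and YBX1 (0.701%) were among the 12 most abundant transcripts, and all lie on chromosome 1 between 40040240 and 42703805.

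Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 7804 genes by edgeR and the highest of the others 0 (601 at an unadjusted p under 0.05). Only 1 split, the real one, called as many. Every other split mixes both groups, so the group difference enters its spread and few gene calls were likely from the start. The contrast also cannot tell an effect of ultrasound from another difference between the groups. For lists, the real split called 22 by camera with the preset correlation and the highest of the others 16, and again 1 split called as many. The other splits called between 7 and 16 lists each, though they called 0 genes. Camera with the preset correlation can thus call many lists where no gene is called. These splits still hold part of the group difference, so they do not give its rate of false calls.

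More genes were detected in the untreated libraries, which were the shallower ones, and this direction argues against depth. Thinned to equal depth, the lowest untreated library detected 4434 genes more than the highest cLIUS library, against a range of at most 917 within a group. Thinning takes most reads from the deeper cLIUS libraries, so it could hardly close the gap and adds little to the argument. Low-level reads over silent genes may contribute: 159 taste receptor, vomeronasal receptor and beta-defensin genes together took 1.78 times as much of the untreated as of the cLIUS libraries. The margin of this sum was small, since cLIUS replicate 2 (6.13 CPM) came close to the lowest untreated library (6.69 CPM). Vomeronasal receptors alone overlapped. Classes outside this sum differed more clearly. The 405 olfactory receptor genes summed to 20.8 ± 4.21 CPM of the library total in untreated and 6.5 ± 0.67 CPM in cLIUS libraries, without overlap. Of 10 tested, 7 fell and 1 rose. The 112 keratin-associated protein genes summed to 0.749 ± 0.0984 and 0.356 ± 0.0782 CPM, also without overlap. Whether such reads come from genomic DNA, unspliced RNA or wider transcription was not tested, and an effect of ultrasound stays open.

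Ribosomal protein genes were higher in the cLIUS group (34 of 76 passed), whose libraries also differed in their trend with gene length and GC content. They took 5.292% of counts in cLIUS replicate 1 and 4.322% in replicate 3, but 3.489% in replicate 2, within the untreated range (3.415% to 3.581%). After correction for both, the list median was 0.394 (0.480 before; camera adjusted p = 3.36e-06, and 2.23e-06 before), which argues against the trend as the whole cause. Without cLIUS replicate 1, the library with the steepest trend, the median was 0.290 (camera adjusted p = 1.36e-04). This argues against replicate 1 alone as the whole cause, though the median fell. It does not exclude that the remaining rise rests on replicate 3, since replicate 2 lay within the untreated range by share of counts. The genes of this list move almost as 1 unit (estimated correlation 0.99), and the list is not called with that correlation (camera adjusted p = 0.68) or by fry (adjusted p = 0.148). An effect of ultrasound and a difference of preparation stay open.

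IL1B, INHBA and SPP1 were lower while the neutrophil and myeloid progenitor lists were higher, though both lists lost their calls with an estimated correlation (camera adjusted p = 0.13 and 0.24). Dilution of the macrophages by another cell population is a candidate explanation and predicts lower macrophage differentiation genes. Their median was 0.431, which lies 4.31 above that of the 3 genes (-3.88), more than its interquartile range of 1.69. The 3 genes were picked from the strong falls in these same data, and SPP1 is itself in the list, so a wide gap was likely from the start. The values show that the list as a whole did not fall as these 3 genes did, and they do not decide on dilution. Dilution, also tested against a bound of -1, stays open, because the bound lies within that interquartile range of the median. A population that itself expresses macrophage genes stays open too. The hypothesis of lower ERK pathway output was tested on 5 genes whose values had not been seen, of which 4 passed the filter: CCND1 fell by 2.71 and ETV4 by 1.29 (log2), ETV5 rose by 0.67 and EPHA2 was at 0.77 (not called). Their median of -0.311 with 2 called lower met neither the bound set for this hypothesis nor that set against it, and an effect of ultrasound by another route stays open.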
